A study of Mus musculus with 16 samples.

How the data were processed

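Epididymal white fat, the visceral fat pad that lies along the epididymis, was profiled by sequencing of total RNA in 16 libraries from male C57BL/6 mice. Per the labels, 4 libraries came from each of 4 groups: a normal diet, a high-fat diet (HFD), HFD with metformin (an antidiabetic biguanide) and HFD with resveratrol (a plant polyphenol). Mice were 6 weeks old and about 22 g when purchased, the HFD contained 60% fat and ran for 8 weeks before treatment, and both drugs were given for 6 weeks. The sample titles, source name and design text name epididymal fat, while the extraction text speaks of retina and the treatment text of skeletal muscle. Markers of both tissues were therefore included among the gene lists. The titles give each library its own code, and the p-values measure the spread between these libraries. Some codes of a group share their first number, which may or may not mark a cage or batch, and the libraries were treated as separate replicates.

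Per the file headers, the deposited tables held raw whole-number counts per mRNA transcript and per lncRNA transcript (long non-coding RNA), with FPKM values of the authors beside them. The submitters' processing notes name fastp, HISAT2 and genome build GRCm38, without role or version. The counting tool, the annotation release, the strand setting and the filters are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be told apart. In the mRNA table the header had 1 name fewer than the lines had cells, and 5 records were broken over 2 lines and were rejoined. The assignment of headers to values was checked with the library total that FPKM, counts and transcript lengths imply. For 14 libraries the total implied by the lncRNA table differed from the summed counts of both tables by at most 0.0418%. With the mRNA count of any other library in place of its own, the smallest difference was 0.492%. The FPKM values were used for this check alone.

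Of the 16 count columns in each table, 14 matched a sample title. The other 2 carried an animal code found in no title, and their code prefix gave the group only, 1 in HFD and 1 in HFD with metformin. They were kept as replicates of those groups, a choice made after the tables had been opened, and are called HFD unmatched and metformin unmatched. The remaining libraries are called by group and replicate number. A further 4 columns of per-sample values, the FPKM columns of those codes, were not used.

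Counts of 91879 mRNA transcripts were summed to 27150 genes by gene identifier, of which 54 gene names were carried by more than 1 identifier. Counts of 77985 lncRNA transcripts, 10325 from Ensembl, 67443 from NONCODE and 217 assembled by the authors, gave 76125 features after transcripts sharing an Ensembl name were summed. Totals ranged from 13350585 to 20531032 mRNA counts and from 3550737 to 5828645 lncRNA counts per library. Pairs of libraries within a group differed by more than sampling noise, with a chi-square of 13.6 to 551 per degree of freedom over genes. None was treated as a repeated deposit.

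Genes were tested with edgeR 4.0.16 in R 4.3.3. A robust quasi-likelihood model was fitted to all 16 libraries with group as the factor, after the tool's filter on low counts and TMM normalisation. It left 17337 genes and 22774 lncRNAs. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over all features tested in a comparison, with 0.05 as the threshold. The lncRNA model took its library sizes and TMM factors from the mRNA table. Expression levels are TMM-normalised CPM, given as mean ± SD over the n = 4 libraries of a group unless another n is stated, and log2 fold changes carry the standard error (SE) of the model. CPM of lncRNAs are relative to the mRNA total, and summed CPM of marker lists to the library's mRNA count without a TMM factor.

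A total of 35 gene lists of pathways, cell types and other tissues was tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated correlation. P-values were adjusted over the lists of a comparison. Camera asks whether a list moved relative to all other genes. Each list also has a count of members past the threshold over all genes and a count adjusted over the list alone. For each list a score per library, the mean z-score of log2 CPM (prior count 2), was compared between groups with an exact two-sided permutation test over 70 assignments, for which 0.0286 is the smallest possible p. A further 3 lists, of motile ciliated epithelium, epididymis principal cells and spermatogenic cells, were written after transcripts of the male reproductive tract had been seen, and were adjusted among themselves, except in the permutation test, where all lists were adjusted together. The epididymis principal cell list was taken from the fixed list of epididymis and testis markers, which also holds 8 of the 23 spermatogenic genes.

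Genes are named by a rule: the 8 largest increases and decreases with at least 5 CPM and non-overlapping groups, the 2 members of each list with the smallest adjusted p, and a set of adipose genes given in every case. Some results that the rule takes are not reported here. For lncRNAs the 5 largest with at least 1 CPM were taken, with members of a list of known lncRNAs. The groups, tests, lists, naming rule and a first set of other settings were fixed before the data were examined. These settings were DESeq2 1.42.0, RLE normalisation, no filter, a filter at a mean of 5 CPM, a fit of the 2 groups alone, 1 surrogate variable (sva 3.50.0), a 2-fold threshold and leaving out each library of the groups compared. Settings meant for normalised values were not needed, since counts were given. Added after the data were seen were fits without resveratrol 4, without both unmatched libraries, without both kinds, without resveratrol 4 and metformin 2, and without the 6 libraries rich in tract transcripts. A fit with scores of the ciliated and spermatogenic lists as covariates, which also left out resveratrol 4, fits without each library of the groups not compared, and TMM factors of the lncRNA table itself were also added.

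Comparisons that share the HFD libraries were set beside 100 simulations of unchanged groups and 6 halvings of those libraries. Overlaps of calls were set beside 50 simulations with a full fit each. The scripts were tested on simulated data for HFD against normal diet over 17337 genes, 200 of them changed. At the spread of all 16 libraries, 22% of 2-fold and 63% of 4-fold changes were found, 100% of them in the right direction, with 2 unchanged genes called. At the spread without resveratrol 4 these shares were 32% and 73%. Gene positions are those of the deposited tables, in GRCm38.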

Results

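Coding and long non-coding transcripts of epididymal fat were measured in 16 libraries, 4 per group. Total mRNA counts were 13350585, 18036060, 18322401 and 17498477 in the normal diet libraries 1 to 4. They were 20297488, 20168711, 20531032 and 17025308 in HFD 1, 2, 3 and unmatched, 15061324, 15260893, 19567404 and 17648725 in metformin 1, 2, 4 and unmatched, and 17150115, 13734379, 16858297 and 13865342 in resveratrol 1 to 4. The first principal component held 49.2% of the variance and set normal diet 2, metformin 2, 4 and unmatched and resveratrol 2 and 4 apart from the other 10 libraries. The second, with 16.8%, set resveratrol 4 apart, and the third, with 9.77%, placed HFD 1 to 3 at one end. The median Spearman correlation of resveratrol 4 with the other libraries was 0.771, that of metformin 2 was 0.859, and those of the other 14 lay between 0.927 and 0.976.

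Transcripts of fat cells and of neighbouring tissue differed between libraries of the same group. Adipocyte markers such as Adipoq and Plin1 summed to 33468 to 65202 CPM in 15 libraries and to 2248 CPM in resveratrol 4. In that library, genes of epididymis principal cells (Crisp1, Adam7 and others) summed to 30479 CPM, against 0.411 to 110 CPM in 14 others and 297.5 CPM in normal diet 4, where the seminal vesicle gene Svs2 alone made up 294.9 CPM. Crisp1, a secreted protein of the epididymis, had 11511 CPM in resveratrol 4 and 14.7 to 16.1 CPM in the 4 metformin libraries. It was below 0.2 CPM in all others. Genes of motile ciliated epithelium such as Foxj1 and Dnah5 summed to 1208 CPM in normal diet 2, 1649, 603 and 897 CPM in metformin 2, 4 and unmatched, and 751 CPM in resveratrol 2, against 54.6 to 152 CPM in the other 11. Spermatogenic cell genes, among them the sperm protamine Prm2, summed to 3217 CPM in metformin 2 and 959 CPM in resveratrol 4. Retina markers summed to 12.6 to 54.3 CPM and skeletal muscle markers to 86.5 to 394 CPM.

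**Figure D1:**
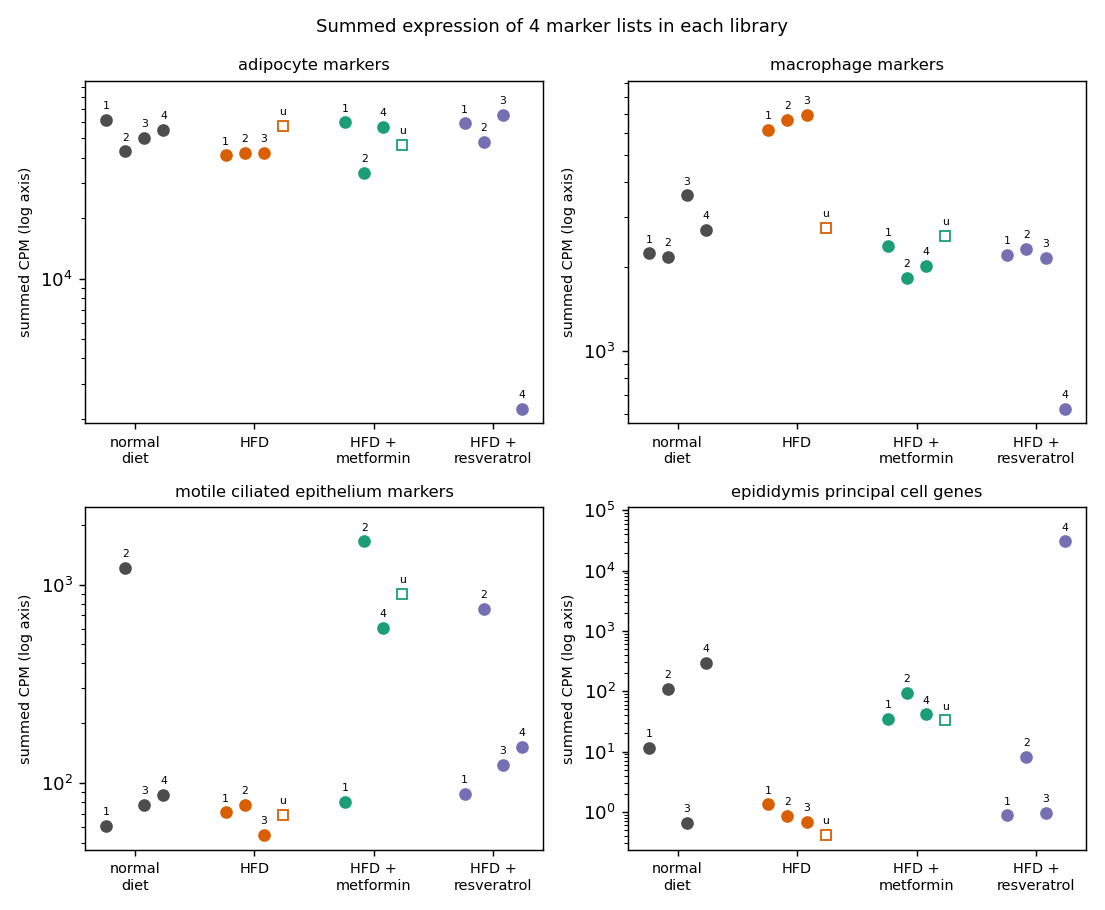
Summed expression of 4 marker lists in each library, in CPM of the library's mRNA count on log axes, with points labelled by replicate number and open squares marked u for libraries whose code matched no title. Resveratrol 4 had 2248 CPM of adipocyte markers and 30479 CPM of epididymis principal cell genes, and macrophage markers had 6135 to 6922 CPM in HFD 1 to 3 against 2750 CPM in HFD unmatched.

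High-fat feeding was compared with the normal diet to ask what it changed in this fat pad. Leptin (Lep, chromosome 6, 29060220 to 29073877 in GRCm38, as for all positions given), the hormone that fat cells secrete in proportion to their stores, rose from 403 ± 285 to 3184.5 ± 976 CPM (7.9-fold, log2 fold change 2.98, SE 0.67, adjusted p = 0.018). Itgax (chromosome 7, 128129547 to 128150657), which encodes CD11c of dendritic cells and of macrophages in obese fat, rose from 14.1 ± 12.3 to 193 ± 108 CPM (13.6-fold, log2 3.77, SE 0.73, adjusted p = 0.0101). Insig1 (chromosome 5, 28071363 to 28078662), a regulator of sterol synthesis, rose from 96.1 ± 7.51 to 518 ± 200 CPM (log2 2.43, SE 0.30, adjusted p = 0.00179). The complement factor adipsin (Cfd, chromosome 10, 79890853 to 79892655), a product of fat cells, fell from 5948 ± 1301 to 891 ± 600.2 CPM (log2 -2.74, SE 0.78, adjusted p = 0.0429).

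Of 17337 genes, 921 rose and 610 fell. The small structural RNAs Rn7s1, Rn7s2, Rn7sk, Rmrp and Rpph1 of the lncRNA table made up 6.20 to 8.23% of all counts in the HFD libraries and 5.22 to 5.95% in those on the normal diet. Mitochondrial mRNA made up 0.833 to 1.16% and 1.42 to 2.08% of mRNA counts. Among the largest increases were Tph2, a tryptophan hydroxylase of serotonin synthesis, from 0.281 ± 0.134 to 59.3 ± 41.5 CPM (chromosome 10, 115078641 to 115185022, log2 7.73, SE 0.92, adjusted p = 0.0017), and the choline transporter Slc5a7, from 2.0 ± 0.398 to 162 ± 72.5 CPM (log2 6.34, SE 0.80, adjusted p = 0.0021). Ubd, an inflammation-induced ubiquitin-like protein, rose from 0.744 ± 0.115 to 42 ± 25.1 CPM (log2 5.80, SE 0.77, adjusted p = 0.0024). Among the largest decreases was the transcription factor Irf4, from 169 ± 76 to 20.8 ± 2.41 CPM (log2 -3.03, SE 0.73, adjusted p = 0.0236). Sirt1, an NAD-dependent deacetylase, fell from 19.9 ± 1.99 to 12.3 ± 0.899 CPM (log2 -0.70, SE 0.19, adjusted p = 0.036), and Ppargc1a, a coactivator of mitochondrial genes, fell from 14.6 ± 5.73 to 4.3 ± 1.14 CPM (log2 -1.76, SE 0.37, adjusted p = 0.0141). Adiponectin (Adipoq) had 2775 ± 817 and 2377 ± 491 CPM (adjusted p = 0.88), and Slc2a4, Pparg, Fasn, Scd1 and Prkaa2 did not pass the test either (adjusted p = 0.489, 0.93, 0.756, 0.505 and 0.0907). Ucp1, the uncoupling protein of brown fat, had too few counts to be tested.

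Several immune lists rose with high-fat feeding. Of 25 lipid-associated macrophage genes, 13 rose and 0 fell, or 19 adjusted over the list alone (camera adjusted p = 3.84e-10, and adjusted p = 0.476 with an estimated correlation). Of 27 macrophage markers, 7 rose, or 15 adjusted over the list alone (adjusted p = 1.09e-04, and adjusted p = 0.886 with an estimated correlation). Examples were the lectin Lgals3, from 106 ± 69.4 to 568 ± 288 CPM (log2 2.42), and Adgre1, which encodes F4/80, from 82.5 ± 25.6 to 311 ± 134 CPM (log2 1.91). In HFD unmatched, Adgre1 had 115 and Itgax 37.1 CPM, against 338 to 402 and 204 to 271 CPM in HFD 1 to 3. The scores of the macrophage, lipid-associated macrophage and cytokine lists in HFD unmatched (0.174, 0.0224 and 0.269) lay below those of normal diet 3 (0.466, 0.261 and 0.342). The cytokine and chemokine list rose (adjusted p = 0.0227, and adjusted p = 0.886 with an estimated correlation), with 5 members up and 1 down of 29, or 6 and 1 adjusted over the list alone. It lost the call without normal diet 4 or HFD 3 (0.0537 and 0.0524). Ccl2 went from 1.87 ± 0.769 to 12.3 ± 3.82 CPM (log2 2.71, SE 0.59, adjusted p = 0.0157) and Tnf from 0.402 to 1.82 ± 0.548 CPM (log2 2.14, adjusted p = 0.0173). Antigen presentation genes rose (4 of 17, or 9 adjusted over the list alone, adjusted p = 2.30e-04, and adjusted p = 0.812 with an estimated correlation), for instance Tapbp (log2 0.74) and H2-DMb1 (log2 1.75). Of 28 interferon-stimulated genes, 2 rose, Ifit3b (log2 1.33) and Oas1a (log2 1.23), or 4 adjusted over the list alone (adjusted p = 8.43e-05, and adjusted p = 0.687 with an estimated correlation).

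Growth, matrix and lipid lists also rose. Of 26 cell cycle genes, 7 rose, or 18 adjusted over the list alone (adjusted p = 7.64e-13, and adjusted p = 0.476 with an estimated correlation), among them the kinase Cdk1 (log2 2.08) and the replication factor Mcm5 (log2 1.78). Of 25 cholesterol synthesis genes, 9 rose, or 13 adjusted over the list alone (adjusted p = 4.51e-07, and adjusted p = 0.334 with an estimated correlation), including the last enzyme of the pathway, Dhcr7 (7.04 to 23.1 ± 7.5 CPM, log2 1.71). Of 37 extracellular matrix genes, 4 rose, or 7 adjusted over the list alone (adjusted p = 6.52e-04, and adjusted p = 0.886 with an estimated correlation), for instance Col12a1 (log2 1.60) and Col6a2 (log2 1.56). In HFD unmatched the cell cycle and matrix scores (0.213 and 0.255) lay below those of normal diet 3 (0.355 and 0.326), while in HFD 1 to 3 they were 1.11 to 1.31 and 0.750 to 0.892. Of 15 adipocyte hypertrophy genes, 4 rose by either adjustment, the second adjusted over the list alone (adjusted p = 0.0427, and adjusted p = 0.886 with an estimated correlation), Lep and the Wnt antagonist Sfrp5 (log2 2.91) among them. This list lost the call without normal diet 1, 2 or 3 (0.0520, 0.0744 and 0.0711), HFD unmatched (0.0824) or metformin 1 or 2 (0.0506 and 0.0620).

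Lists that fell were circadian clock genes (3 of 19, or 4 adjusted over the list alone, adjusted p = 7.09e-04, and adjusted p = 0.184 with an estimated correlation), with Per1 from 189 to 88.5 CPM (log2 -1.10, SE 0.15), and branched-chain amino acid breakdown (3 of 21, or 4 adjusted over the list alone, adjusted p = 0.00982, and adjusted p = 0.886 with an estimated correlation), with Aldh6a1 (log2 -0.95) and Hsd17b10 (log2 -1.03). The branched-chain score was -0.646 to -0.367 in HFD 1 to 3. In HFD unmatched it was 0.314, above normal diet 2 (-0.112) and below the other normal diet libraries (0.461 to 0.893). Mesothelial markers fell as a list with 0 of 17 members past the test by either adjustment, the second adjusted over the list alone (adjusted p = 0.00734, and adjusted p = 0.886 with an estimated correlation). Their score was -0.404 to -1.17 in HFD 1 to 3 and 0.893 in HFD unmatched, above the 0.330 to 0.670 of the normal diet libraries. The 11 known lncRNAs in the mRNA table fell (3, or 5 adjusted over the list alone, adjusted p = 0.00628, and adjusted p = 0.184 with an estimated correlation). Some lists with no call held genes that changed. In de novo lipogenesis (list adjusted p = 0.599) the desaturase gene Scd2 rose from 124 ± 86.6 to 1075 ± 439 CPM (adjusted p = 0.0319) and Pgd rose from 168 to 429 CPM. In triglyceride synthesis and lipolysis (0.554) Dgat2 rose from 221 ± 92.3 to 1218 ± 132 CPM (log2 2.46, SE 0.47, adjusted p = 0.00948). In insulin signalling (0.679) the insulin receptor Insr fell from 404 ± 39.2 to 231 ± 41.5 CPM (log2 -0.81, SE 0.18, adjusted p = 0.0187).

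The other lists were not called in this comparison. Their adjusted p-values were 0.0523 for liver, skin, pancreas, kidney and gut markers, 0.0668 for AMPK, sirtuin and PGC-1 genes, 0.082 for red blood cell markers, 0.0847 for endoplasmic reticulum stress, 0.134 for smooth muscle and pericyte markers, 0.18 for epididymis and testis markers, 0.393 for skeletal muscle, 0.51 each for fatty acid oxidation and for neutrophil, mast and dendritic cells, and 0.554 for immediate early genes. They were 0.599 for endothelial, 0.603 for fibroblast and preadipocyte, 0.633 for thermogenic, 0.679 for T and NK cell, 0.709 for oxidative phosphorylation, 0.838 for NRF2 target, 0.864 each for adipocyte and retina, and 0.945 for B cell lists. Of the added lists, the ciliated epithelium had 0.101, epididymis principal cells 0.405 and spermatogenic cells 0.661. The thermogenic list tested up with a median of -0.15 and a mean of -0.10, NRF2 targets tested up with a mean of -0.09, and insulin signalling tested down with a median of 0.03. The count of 1531 genes fell to 375 without HFD 3, 494 without HFD 1, 499 without HFD 2, and 601, 566 and 695 without normal diet 1, 2 and 4. It was 4050 without resveratrol 4, 1531 of them shared, and 3129 with DESeq2.

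**Figure D2:**
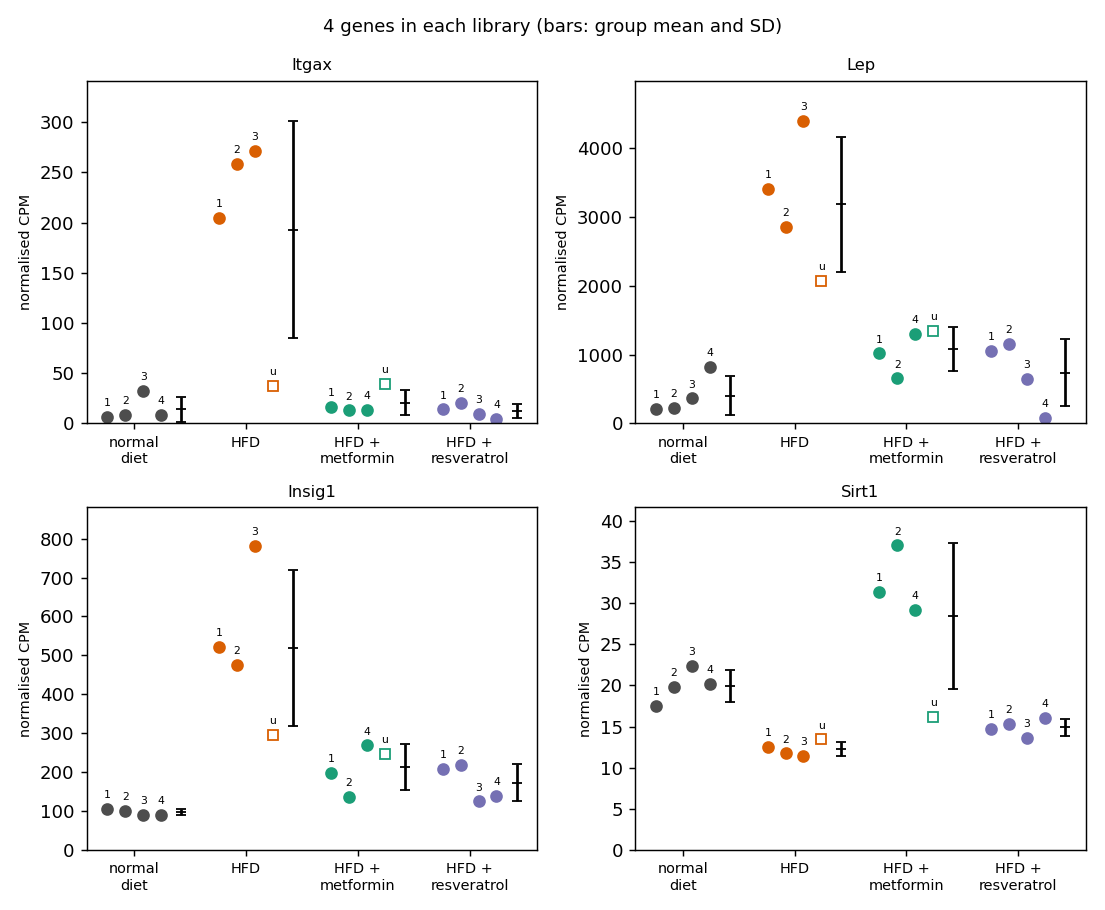
Normalised CPM of Itgax, Lep, Insig1 and Sirt1 in each library, with black bars for the group mean ± SD (n = 4), points labelled by replicate number and open squares marked u for libraries whose code matched no title. Itgax was 193 ± 108 CPM on HFD and 20.5 ± 12.6 and 12.1 ± 6.81 CPM with metformin and resveratrol, with HFD unmatched at 37.1 CPM.

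Metformin on the HFD was compared with HFD alone. Macrophage genes were lower: Itgax fell from 193 ± 108 to 20.5 ± 12.6 CPM (log2 -3.23, SE 0.71, adjusted p = 0.0494), and Trem2 (chromosome 17, 48346401 to 48354147), a lipid receptor of macrophages, fell from 113 ± 66.7 to 9.28 ± 3.51 CPM (log2 -3.61, SE 0.79, adjusted p = 0.0494). Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, fell from 926 ± 549 to 63 ± 36.7 CPM (log2 -3.88, SE 0.76, adjusted p = 0.0471). Metformin unmatched had 39.3, 14.5 and 118 CPM of Itgax, Trem2 and Gpnmb. HFD unmatched had 37.1, 16.1 and 126 CPM, so the groups overlapped for Itgax and were close for the others. Sirt1 (chromosome 10, 63319005 to 63381704) rose from 12.3 ± 0.899 to 28.5 ± 8.83 CPM (2.32-fold, log2 1.21, SE 0.19, adjusted p = 0.0471), against 19.9 ± 1.99 CPM on the normal diet. Metformin 1, 2 and 4 had 31.4, 37.1 and 29.2 CPM of Sirt1. Metformin unmatched had 16.2 CPM, above the HFD libraries (11.4 to 13.4 CPM) and below the normal diet libraries (17.5 to 22.3 CPM). Ppargc1a (chromosome 5, 51454250 to 51567726) rose from 4.3 ± 1.14 to 14.1 ± 4.28 CPM (log2 1.72, SE 0.37, adjusted p = 0.0494). Ppargc1a had 15.3, 17.1 and 16.3 CPM in metformin 2, 4 and unmatched. Normal diet 2 had 22.3 CPM and resveratrol 2 had 17.4 CPM, and all of these libraries were rich in ciliated epithelium genes. Metformin 1 had 7.82 CPM, and the HFD libraries had 2.80 to 5.415 CPM. Normal diet 1, 3 and 4, with 60.6 to 86.9 CPM of ciliated epithelium genes, had 14.6, 12.8 and 8.64 CPM of Ppargc1a. Resveratrol 1, 3 and 4 had 8.12, 6.58 and 11.6 CPM of it. High levels were thus not confined to libraries rich in ciliated epithelium genes. With covariates for tract transcripts and without resveratrol 4 the log2 fold change of Ppargc1a was 0.91 (adjusted p = 0.0957). In that setting Itgax, Trem2 and Gpnmb had log2 fold changes of -3.09, -3.41 and -3.83 and lost the call as well (adjusted p = 0.0755, 0.0957 and 0.0716). Of 20 called genes examined in this way, 17 lost it (0.0581 to 0.108), while Sirt1, Agt and Ubd passed (0.0498, 0.0472 and 0.0406). Without resveratrol 4 and with no covariates, Itgax, Trem2 and Gpnmb had log2 fold changes of -3.24, -3.62 and -3.89. The score of the ciliated list was 0.855 to 1.77 in metformin 2, 4 and unmatched and -0.686 to -0.603 on HFD. This covariate was thus partly confounded with the comparison, and a lost call does not show that a change came from tract transcripts. Without the 6 libraries rich in tract transcripts only metformin 1 was left of the metformin group, so effect sizes alone are given. The log2 fold changes of Sirt1, Ppargc1a, Itgax, Trem2 and Gpnmb were then 1.35, 0.86, -3.58, -3.89 and -4.27.

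In all, 32 genes rose and 147 fell. The small structural RNAs made up 4.30 to 5.99% of all counts with metformin, below all HFD libraries, and mitochondrial mRNA 1.01 to 1.42% of mRNA counts. Agt, the angiotensin precursor, rose from 59.5 ± 24.3 to 206 ± 74.4 CPM (log2 1.79, SE 0.33, adjusted p = 0.0471). Tph2 fell to 2.56 ± 1.79 CPM (log2 -4.53, SE 0.77), Ubd to 3.09 ± 1.31 CPM (log2 -3.76), and Atf3, a stress-response transcription factor, from 87.6 ± 48 to 10 ± 4.18 CPM (log2 -3.13). Bbof1 (1.78 to 17.7 ± 21.5 CPM, log2 3.31), a ciliary gene, rose as well; ciliated epithelium genes summed to 603 to 1649 CPM in 3 of the 4 metformin libraries and to 54.6 to 77.5 CPM on HFD. With the covariates and without resveratrol 4 the log2 fold change of Bbof1 was 1.28 (adjusted p = 0.0658). Lep had 1079 ± 319 CPM (log2 -1.56, SE 0.63, adjusted p = 0.154), Adgre1 78.1 ± 17.8 CPM (adjusted p = 0.0564), Ccl2 3.5 CPM (adjusted p = 0.1) and Tnf an adjusted p of 0.074. Without resveratrol 4 these 4 passed, with adjusted p = 0.0342, 0.012, 0.0163 and 0.0325. With the covariates added to that fit none of them passed (0.189, 0.0685, 0.108 and 0.109), at log2 fold changes of -1.25, -1.62, -1.21 and -1.21. Adipoq (2365 ± 877 CPM, log2 -0.01, adjusted p = 0.998), Slc2a4, Pparg, Fasn, Scd1 and Prkaa2 (0.982, 0.937, 0.501, 0.78 and 0.165) did not pass.

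Macrophage, antigen presentation and cytokine lists fell. Of lipid-associated macrophage genes, 0 rose and 5 of 25 fell, or 20 adjusted over the list alone (camera adjusted p = 7.45e-13, and adjusted p = 0.590 with an estimated correlation), among them the lysosomal lipase Lipa, from 433 ± 193 to 114 ± 25.6 CPM (log2 -1.93, SE 0.35). Of macrophage markers, 4 of 27 fell, or 17 adjusted over the list alone (adjusted p = 7.38e-10, and adjusted p = 0.590 with an estimated correlation), with Lgals3 at 84.6 ± 19.3 CPM (log2 -2.75) and the Fc receptor Fcgr1 from 14 to 4.94 CPM. HFD unmatched, at 2750 CPM of macrophage markers, lay nearer to the metformin libraries (1829 to 2580 CPM) than to HFD 1 to 3 (6135 to 6922 CPM). Antigen presentation fell with 1 of 17, Tapbp (log2 -0.62, and -0.39 with adjusted p = 0.0703 under these covariates), or 9 adjusted over the list alone (adjusted p = 1.65e-07, and adjusted p = 0.590 with an estimated correlation), and cytokines with 1 of 29, Tgfb1 (84.7 to 43.1 CPM), or 6 adjusted over the list alone (0.00234, and adjusted p = 0.627 with an estimated correlation). Cell cycle genes fell with 1 of 26, Pcna (60.3 to 31.5 CPM), or 2 adjusted over the list alone (3.25e-06, and adjusted p = 0.627 with an estimated correlation). Their score in metformin 2, which had 3217 CPM of spermatogenic cell genes, was 1.49 and above all HFD libraries (0.213 to 1.31), and in the other 3 metformin libraries it was -0.629 to -0.121.

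Cholesterol synthesis fell with 2 of 25, Insig1 (213 ± 58.8 CPM, log2 -1.29) and Dhcr7 (11.3 ± 0.9 CPM, log2 -1.04), or 7 adjusted over the list alone (9.81e-04, and adjusted p = 0.590 with an estimated correlation). Extracellular matrix genes fell with 0 members past the test and 0 adjusted over the list alone (7.42e-05, and adjusted p = 0.764 with an estimated correlation). Endoplasmic reticulum stress fell with 1 of 22, Atf3, or 2 adjusted over the list alone (0.00234, and adjusted p = 0.590 with an estimated correlation), and immediate early genes with 1 of 26, or 6 adjusted over the list alone (0.0129, and adjusted p = 0.627 with an estimated correlation). Clock genes rose with 1 of 19, or 3 adjusted over the list alone (0.0133, and adjusted p = 0.590 with an estimated correlation). Their score was 0.191 to 0.386 in metformin 2, 4 and unmatched and 0.306 in resveratrol 2, all rich in ciliated epithelium genes. It was -0.106 in metformin 1 and -0.324 to -0.192 in the other resveratrol libraries, against -0.717 to -0.220 on HFD. Normal diet 2, also rich in these genes, had 0.579. Normal diet 1, 3 and 4, which were not, had -0.0775, 0.383 and 0.791, so high scores were not confined to such libraries. A further 3 lists rose with 0 members past the test over all genes: liver and similar markers (8 up and 1 down of 10 adjusted over the list alone, 2.43e-04, and adjusted p = 0.590 with an estimated correlation), B cell markers (2 up and 1 down adjusted over the list alone, 0.00348, and adjusted p = 0.629 with an estimated correlation) and epididymis and testis markers (1 adjusted over the list alone, 0.00142, and adjusted p = 0.642 with an estimated correlation). The B cell list lost the call without metformin 1 (0.0669), and immediate early genes without metformin 2 or resveratrol 4 (0.0574 and 0.0511). The added lists rose too, with adjusted p = 1.85e-08 for ciliated epithelium, 0.00141 for spermatogenic cells and 0.015 for epididymis principal cells, and adjusted p = 0.313 with an estimated correlation for each. Among lists without a call, the NRF2, hypertrophy, adipocyte, endothelial, mesothelial, oxidative phosphorylation, smooth muscle and triglyceride lists had a median or mean of the opposite sign to the test.

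The adjusted p-values of the genes named as changed lay between 0.0471 and 0.0494, close to the threshold, and the count of 179 moved between fits. It was 1, 0 and 0 without HFD 1, 2 and 3, and 0, 0, 1 and 1 without metformin 1, 2, 4 and unmatched. It was 713 without HFD unmatched and 2442 without resveratrol 4 (1068 up and 1374 down, 179 shared). The fit takes its spread from all groups, and the count was also 0 without normal diet 1, 2 or 4 or resveratrol 1, 2 or 3. It was 0 with no filter or with a surrogate variable and 2234 with DESeq2 (1292 up and 942 down). Without the 6 libraries rich in tract transcripts it was 18 (2 shared), with 1 metformin library left and assumed to vary like the other groups. With covariates for tract transcripts and without resveratrol 4 it was 72 (14 shared).

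Resveratrol on the HFD was compared with HFD alone. Itgax fell from 193 ± 108 to 12.1 ± 6.81 CPM (log2 -4.00, SE 0.74, adjusted p = 0.0289), and Mmp12 (chromosome 9, 7344381 to 7369499), the macrophage elastase, fell from 270 ± 152 to 10.9 ± 8.86 CPM (log2 -4.63, SE 0.99, adjusted p = 0.033). Mpeg1, a pore-forming protein of phagocytes, fell from 593 ± 258 to 89.3 ± 30.6 CPM (log2 -2.73, SE 0.46, adjusted p = 0.0289), and Adgre1 fell to 64.2 ± 31.2 CPM (log2 -2.27, SE 0.46, adjusted p = 0.0294). Insig1 fell from 518 ± 200 to 173 ± 47.7 CPM (log2 -1.59, SE 0.29, adjusted p = 0.0289).

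In total 87 genes rose and 308 fell. The small structural RNAs made up 6.00 to 6.75% of all counts, and mitochondrial mRNA 1.34 to 2.03% of mRNA counts, above all HFD libraries. Tph2 fell to 1.3 ± 0.59 CPM (log2 -5.50, SE 0.81), Gpnmb to 40.6 ± 16.5 CPM (log2 -4.51, SE 0.78), the acute-phase gene Saa3 from 28.3 to 1.27 CPM (log2 -4.47), Lgals3 to 88.3 ± 26 CPM (log2 -2.68) and Tnf to 0.321 CPM (log2 -2.47, SE 0.49, adjusted p = 0.0291). Without resveratrol 4 (n = 3) all 5 passed again, with adjusted p = 0.035, 0.036, 0.0416, 0.0365 and 0.0371 in this order. Gsta4, a glutathione transferase for lipid aldehydes, rose from 5.07 ± 4.04 to 16.6 ± 2.5 CPM (log2 1.72, SE 0.39, adjusted p = 0.0391), and Aldh6a1 rose to 870 ± 232 CPM (log2 0.90, adjusted p = 0.0474, and 0.055 without resveratrol 4). The largest increase was set by resveratrol 4. Ces5a (chromosome 8, 93499064 to 93535830), a carboxylesterase of the epididymis, had 0.0254 CPM on HFD, 3987 CPM in resveratrol 4 and 0.125 ± 0.101 CPM in the other 3 (adjusted p = 0.0482, and 0.194 without resveratrol 4). Slc44a4 and Lama1 lost the call without that library (log2 7.46 and 4.07, adjusted p = 0.056 and 0.0722). With covariates for tract transcripts added they passed without it, at log2 fold changes of 4.36 and 2.26. All 16 libraries gave 10.4 and 7.81. Slc44a4 had 0 to 0.102 CPM on HFD, 17.4 CPM in resveratrol 2 and 0.303 and 0.384 CPM in resveratrol 1 and 3. Lama1 had 0.101 to 0.625 CPM on HFD, 13.9 CPM in resveratrol 2 and 1.09 CPM in resveratrol 1 and in resveratrol 3. Gpx3, a secreted glutathione peroxidase, rose with resveratrol 4 (837 ± 1143 CPM) and without it (266 ± 43.3 CPM against 112, log2 1.24, adjusted p = 0.036). Lep had 735 ± 488 CPM (log2 -2.12, SE 0.65, adjusted p = 0.0817), Ccl2 3.63 ± 2.58 CPM (adjusted p = 0.0912), Sirt1 14.9 ± 1.04 CPM (log2 0.28, SE 0.19, adjusted p = 0.368) and Adipoq 2399 ± 1736 CPM (adjusted p = 0.994).

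Of lipid-associated macrophage genes, 0 rose and 11 of 25 fell, or 21 adjusted over the list alone (camera adjusted p = 5.02e-16, and adjusted p = 0.556 with an estimated correlation). Of macrophage markers, 11 of 27 fell, or 18 adjusted over the list alone (1.18e-13, and adjusted p = 0.556 with an estimated correlation); summed, they had 2148 to 2316 CPM in resveratrol 1 to 3 and 624 CPM in resveratrol 4. Cell cycle genes fell with 3 of 26, Pcna and Mcm6 among them, or 15 adjusted over the list alone (6.19e-11, and adjusted p = 0.556 with an estimated correlation). Antigen presentation fell with 5 of 17, for instance H2-DMb1 (75.8 ± 32.1 to 18.5 ± 9.02 CPM), or 9 adjusted over the list alone (3.82e-09, and adjusted p = 0.556 with an estimated correlation), and cytokines with 4 of 29, or 2 up and 9 down adjusted over the list alone (2.29e-05, and adjusted p = 0.556 with an estimated correlation). Cholesterol synthesis fell with 2 of 25, Insig1 and Dhcr7 (9.75 ± 2.06 CPM), or 8 adjusted over the list alone (0.00916, and adjusted p = 0.717 with an estimated correlation). Extracellular matrix genes fell with 0 members past the test and 0 adjusted over the list alone (2.41e-09, and adjusted p = 0.717 with an estimated correlation).

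Further lists fell in a test that held resveratrol 4, in which adipocyte markers summed to 2248 CPM. They were neutrophil, mast and dendritic cell markers (4.08e-04, and adjusted p = 0.561 with an estimated correlation), adipocyte hypertrophy (0.00433), fatty acid oxidation (0.00459), interferon-stimulated genes (0.00916), triglyceride synthesis and lipolysis (0.00916) and adipocyte markers (0.0249), the last 5 with adjusted p = 0.855 with an estimated correlation. Without that library the adjusted p-values were 0.086, 0.396, 0.76, 0.147 and, upward, 0.52 and 0.0393. Without HFD unmatched the interferon, triglyceride and adipocyte lists had 0.0822, 0.0777 and 0.134, and the interferon list had 0.0573 without resveratrol 2. Epididymis and testis markers rose with 1 of 19, Ces5a, or 9 adjusted over the list alone (0.00983, and adjusted p = 0.855 with an estimated correlation), and had 0.381 without resveratrol 4. The added lists rose with adjusted p = 0.00913 for ciliated epithelium, 0.0269 for epididymis principal cells and 0.0467 for spermatogenic cells, each with adjusted p = 0.526 with an estimated correlation. Among lists without a call, the lipogenesis, endoplasmic reticulum stress, immediate early, insulin signalling, oxidative phosphorylation, skeletal muscle and thermogenic lists tested down with a median or mean of the opposite sign.

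The count of 395 genes was 0 without HFD 1, 2 or 3 or resveratrol 1, 2 or 3, 915 without HFD unmatched and 732 without resveratrol 4 (191 up and 541 down, 349 shared). It was 0 in a fit of the 2 groups alone, 2 with a surrogate variable, 17 without the 6 libraries rich in tract transcripts (4 shared), and 2313 with DESeq2 (1156 up and 1157 down). With covariates for tract transcripts and without resveratrol 4 it was 1925. Of 25 called genes examined, 24 passed with these covariates, all but Ces5a, and 0 without the 6 libraries (adjusted p from 0.0800 to 0.186). That last fit kept resveratrol 1 and 3. Its log2 fold changes of Itgax, Gpnmb and Mpeg1 were -4.08, -4.89 and -2.62, against -4.00, -4.51 and -2.73 with all libraries. Those of Ces5a, Slc44a4, Lama1 and Gpx3 shrank to 2.25, 3.36, 1.79 and 1.12, from 14.8, 10.4, 7.81 and 2.91. The count of called genes was 248, 262 and 213 without normal diet 1, 2 and 4, and 248, 193 and 220 without metformin 1, 4 and unmatched. Of the named lists, 7 (both macrophage lists, cytokines, matrix, cell cycle, antigen presentation and cholesterol synthesis) stayed called without resveratrol 4, and cholesterol synthesis lost the call without resveratrol 3 (0.152).

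The drugs were then compared with each other and with the normal diet. Between metformin and resveratrol edgeR called 0 genes, with 1263 at an unadjusted p under 0.05 and 6 called by DESeq2. Sirt1 had 28.5 ± 8.83 CPM with metformin and 14.9 ± 1.04 CPM with resveratrol (log2 0.93, SE 0.19, adjusted p = 0.661). Of the lists, 16 were called, each with 0 members past the test. Liver and similar markers (2.82e-06) and B cell markers (3.23e-05) were higher with metformin, and for both adjusted p = 0.688 with an estimated correlation. The adipocyte, extracellular matrix, triglyceride and endothelial lists were also called higher with metformin (0.0022, 0.00313, 0.0116 and 0.0142, each with adjusted p = 0.688 with an estimated correlation). Without resveratrol 4 these 4 lists were called lower (0.0012, 7.96e-04, 0.00625 and 0.000412), and without metformin 1 none of them was called (0.0921, 0.0550, 0.204 and 0.168). The triglyceride and endothelial lists also lost the call without metformin 4 (0.0686 and 0.0509), and the matrix and endothelial lists without metformin unmatched (0.0612 and 0.0573). The other 10 had adjusted p = 0.688 with an estimated correlation too. Of these, cell cycle genes were higher with metformin (0.0022), but not without metformin 2 (0.770), which was rich in spermatogenic cell genes. Macrophage (0.00598), lipid-associated macrophage (0.0238), cytokine (0.0356), neutrophil, mast and dendritic cell (0.00806), interferon (0.0159), fatty acid oxidation (0.00313), thermogenic (0.00884) and hypertrophy lists (0.0022) were also higher, and endoplasmic reticulum stress was lower (0.00575). Without resveratrol 4 none of these 9 was called (0.226, 0.984, 0.604, 0.963, 0.572, 0.107, 0.382, 0.572 and 0.217 in this order). Without metformin 1 the macrophage, lipid-associated macrophage, cytokine, interferon and oxidation lists also lost the call (0.115, 0.0921, 0.180, 0.180 and 0.110). So did the cytokine, interferon and thermogenic lists without metformin 4 (0.0686, 0.135 and 0.0686). Without metformin unmatched the 2 macrophage lists, cytokines and the neutrophil list had 0.0640, 0.363, 0.258 and 0.0681, and interferon genes had 0.235 without resveratrol 2. Of the added lists, ciliated epithelium was higher with metformin (3.84e-05, and adjusted p = 0.802 with an estimated correlation). The epididymis and testis, epididymis principal cell, fibroblast and mesothelial lists, none of them called, tested up with negative medians and means. Without resveratrol 4, 2 genes were called, the epididymal genes Ces5a and Pate2, named here after their values were seen. Ces5a had 3.88 to 6.12 CPM in the metformin libraries, 0.064 to 0.242 CPM in resveratrol 1 to 3 and 3987 CPM in resveratrol 4. The source of these epididymal transcripts in the metformin libraries was not tested. Against the normal diet, metformin had 1 gene called, A430018G15Rik (also outside the naming rule), from 3.02 ± 0.735 to 0.164 ± 0.0687 CPM (log2 -4.16, SE 0.52, adjusted p = 0.0274), with 1827 at an unadjusted p under 0.05 and 328 by DESeq2. Resveratrol had 0 called by edgeR, 1844 at an unadjusted p under 0.05 and 146 by DESeq2. Without resveratrol 4 these counts were 299 and 26, and the metformin gene lost the call without normal diet 1, 2 or 4, HFD 2, 3 or unmatched, any metformin library, or resveratrol 1 or 3. In the exact permutation test of list scores no list passed after adjustment, with smallest adjusted p-values of 0.136 for HFD against normal diet, 0.0987 and 0.181 for metformin and resveratrol against HFD, and 0.99 between the drugs. With 0.0286 as the smallest possible p, a list could pass only if many others reached that p too, so no conclusion is drawn.

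Across 17337 genes, which are not independent replicates, the fold changes of HFD against normal diet and of metformin against HFD had a Pearson r of -0.73, where unchanged groups sharing the HFD libraries gave -0.50. The covariance was -0.567 against a simulated -0.170. For resveratrol r was -0.77 (simulated -0.50) and the covariance -0.507 (simulated -0.169). With the HFD libraries halved so that none was shared, r was -0.63 and -0.65. Of the genes called in both comparisons, 137 rose on HFD and fell with metformin and 28 fell and rose, with 1 gene changed in the same direction in both. Independent lists would share 7.81 and 1.13. In 50 simulations of unchanged groups no gene was called in both, and lists of the observed lengths, ranked by p, shared 53.3 and 20.0 genes on average (at most 62 and 26) through the HFD libraries alone. With these libraries halved, lists of those lengths shared 121 and 20.5. Genes called in both then numbered only 0 to 8 and 0 to 4, where the comparisons had at most 1015 and 221 calls. For resveratrol, 246 and 64 genes were called in both with all HFD libraries, with 0 in the same direction. Independent lists would share 16.4 and 3.06. Lists of the observed lengths shared 95.2 and 46.6 in the simulations (at most 112 and 54) and 223 and 53.2 with halved libraries. Genes called in both with halved libraries numbered 0 to 20 and 0 to 5, where the comparisons had at most 1015 and 367 calls. Metformin and resveratrol effects had r = 0.83 (simulated 0.50, halved 0.73) and a covariance of 0.700 (simulated 0.169), and 12 genes rose and 117 fell with both. Independent lists would share 0.161 and 2.61, the simulated lists shared 10.4 and 27.4 (at most 16 and 39), and halved libraries gave 8 and 97.8. In no halving was a gene called in both drug comparisons, which then had at most 221 and 367 calls.

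On the scaling of the mRNA table, more long non-coding RNAs fell than rose on HFD, where the small structural RNAs of the same table took 6.20 to 8.23% of all counts against 5.22 to 5.95%. Of 22774 tested, 217 rose and 2775 fell, and the median log2 fold change of all was -0.47. With TMM factors of the lncRNA table itself the median was -0.03 and 369 rose and 250 fell, 447 of them shared. Trp53cor1 (lincRNA-p21, chromosome 17, 29057474 to 29078961), a target of p53, rose from 0.824 ± 0.229 to 5.82 ± 0.383 CPM (log2 2.81, SE 0.42, adjusted p = 0.00269). Neat1, the scaffold of nuclear paraspeckles, fell from 1377 ± 195 to 920 ± 57.7 CPM (log2 -0.58, SE 0.18, adjusted p = 0.0479), and Lncpint fell from 16.5 ± 0.74 to 8.33 ± 1.54 CPM (log2 -0.98, SE 0.18, adjusted p = 0.00527). Snhg1, Snhg12, Snhg18, Mir99ahg, Epb41l4aos and Zfas1 also fell, by 0.62, 1.13, 0.44, 0.84, 1.88 and 0.64 on the log2 scale. The changes of Neat1, Snhg1 and Snhg18 lay within 1 SE of the median of all lncRNAs. Of the NONCODE transcripts, NONMMUT067324.2 (chromosome 8, 115703410 to 115704953, within the span of Maf) had 0.288 ± 0.0733 CPM on the normal diet and 41.3 ± 5.52 CPM on HFD (adjusted p = 0.00638). NONMMUT116144.1 (chromosome 4, 8635209 to 8644880) had 4.72 ± 2.24 CPM on the normal diet and no counts in the 4 HFD libraries (adjusted p = 0.0175). Reads in lncRNAs can belong to overlapping genes, since 66.9% of those tested overlapped the span of an mRNA gene. The count of 2992 was 1711, 1721 and 1736 without normal diet 1, 2 and 3, and 1469, 1632 and 1083 without HFD 1, 2 and 3. It was 5596 without resveratrol 4.

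With metformin 15 lncRNAs rose and 3 fell against HFD, and with resveratrol 364 rose and 61 fell, around medians of 0.31 and 0.36. With factors of the lncRNA table itself, 1 rose and 2 fell and 5 rose and 27 fell, around medians of 0.02 and 0.05. NONMMUT040716.2 (chromosome 2, 156091958 to 156095089) had 25.3 ± 2.18 CPM on the normal diet, 0.284 ± 0.056 on HFD, 22.4 ± 2.86 with metformin (log2 6.27, SE 0.81, adjusted p = 0.0286) and 16.5 ± 10.7 with resveratrol (log2 5.83, SE 0.80, adjusted p = 0.0237). NONMMUT026984.2, within Senp7, had 0.0663 ± 0.0236 CPM on HFD, 2.51 ± 1.62 with metformin and 3.63 ± 0.916 with resveratrol. On the normal diet it was as low as on HFD (0.052 to 0.077 CPM), so its rise with the drugs reversed no HFD change. Metformin 2 had 0.119 CPM of it, against 2.84 to 3.56 CPM in metformin 1, 4 and unmatched. Trp53cor1 fell with resveratrol to 1.65 ± 0.987 CPM (log2 -1.82, SE 0.40, adjusted p = 0.0393). A830008E24Rik rose with resveratrol from 0.598 ± 0.177 to 11.3 ± 18.2 CPM, or to 2.2 ± 0.766 CPM without resveratrol 4 (log2 1.87, adjusted p = 0.0273). NONMMUT014694.2, within Syne2, fell with metformin from 1.91 ± 0.6 to 0.323 ± 0.0896 CPM (log2 -2.54, SE 0.37, adjusted p = 0.0286). Between metformin and resveratrol edgeR called 0 lncRNAs, with 1299 at an unadjusted p under 0.05 and 23 called by DESeq2. The metformin count of 18 was 1 without HFD 1, 2 or 3, metformin 2 or metformin unmatched, 0 without metformin 4, 184 without HFD unmatched and 1239 without resveratrol 4. It was 2, 9 and 2 without normal diet 1, 3 and 4 and 0 without resveratrol 1 or 2. The resveratrol count of 425 was 1 without HFD 1, 2 or 3, 703 without HFD unmatched, 868 without resveratrol 1 and 7 without resveratrol 2. It was 25, 30, 47 and 69 without normal diet 1 to 4, and 219, 100, 97 and 58 without metformin 1, 2, 4 and unmatched.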

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

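The tests on resveratrol 4, on the ciliated epithelium and on the shared code, and the slopes of HFD 1 to 3, were chosen only after the result was seen. A library was singled out where its gap to the next one filled more of its group's range than Dixon's 95% value allows, which chance does in about 1 in 20 groups. Of 176 groups of 4 values examined, 25 had such a library where 8.8 would be found by chance, 12 of them from resveratrol 4 and 5 from HFD unmatched. The values are list scores, each the mean z-score of a list's genes in that library, unless a unit is given.

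Resveratrol 4 was the lowest of its group for adipocyte markers (-3.39), de novo lipogenesis (-0.932), fatty acid oxidation (-2.86), adipocyte hypertrophy genes (-2.82), macrophage markers (-2.30), cytokines and chemokines (-1.53), extracellular matrix (-2.85), endothelial (-3.20), fibroblast (-1.77) and antigen presentation genes (-2.24), and for the share of counts from ribosomal RNA loci (2.37%). It was the highest for epididymis principal cell genes (2.65). HFD unmatched was the highest of its group for adipocyte markers (0.496), triglyceride synthesis and lipolysis (0.615), epididymis and testis markers (-0.254) and spermatogenic cell genes (0.0249), and the lowest in mRNA counts (17.025 M). The other libraries singled out were normal diet 2, lowest for insulin signalling (-0.146) and highest for ciliated epithelium (1.27), normal diet 4, highest for hypertrophy genes (0.148), and normal diet 1, highest for skeletal muscle markers (1.62) and lowest in mRNA counts (13.4 M). Normal diet 3 was the highest for cell cycle genes (0.355), HFD 2 the lowest for neutrophil, mast and dendritic cell markers (0.235) and metformin 2 the lowest for hypertrophy genes (-0.160).

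In resveratrol 4, adipocyte markers were low and epididymal genes high. Low depth is argued against, since the lowest adipocyte sum among libraries with a smaller total was 47781 CPM against 2248 CPM here. A response to resveratrol is argued against by the median of 59303 CPM in the other 3 resveratrol libraries. Epididymis in place of most of the fat is a candidate explanation that the tables leave open, with epididymis genes at 3738 times the median of the other 15 libraries, Crisp1 at 11511 and Adam7 at 5469 CPM, and adipocyte markers at 4.48% of theirs. A mislabelled or exchanged sample was not tested.

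Transcripts of motile ciliated epithelium differed many-fold between libraries of the same group. A response to metformin as the whole cause is argued against by normal diet 2 and resveratrol 2, with 1208 and 751 CPM, and by metformin 1, at 80.4 CPM below normal diet 2 and 4 and every resveratrol library. A lower share of adipocytes is argued against by endothelial and macrophage markers, since the ciliated ratio of highest to lowest library exceeded theirs by at least 7.83 times in each of 3 groups with resveratrol 4 left out. Ciliated cells of another tissue may have been in the sample. The 19 list members not examined before varied together over 15 libraries, with a median pairwise Spearman correlation of 0.861 against at most 0.436 in 1000 random lists of genes. Foxj1, at 97.5 CPM in normal diet 2 and 0.373 CPM or less in the other normal diet libraries, is one of the list's genes, and the tissue was not identified.

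HFD unmatched lay between HFD 1 to 3 and the normal diet, with a slope of 0.487 on their difference over the 1904 genes called without it, where the drug libraries had 0.0519 to 0.398. HFD 1, 2 and 3, each left out in the same way of the gene choice and of the difference of the other 2, had 0.864, 0.925 and 1.04 over 835, 817 and 580 genes. Set against the other 3 HFD libraries they had 1.06, 1.03 and 1.19. A wrong group for this library and a milder response of that mouse cannot be told apart, since its slope was above every drug library but too low to exclude a wrong group by the bound set beforehand, and its code is found in no title. A shared cage or handling of HFD 1 to 3, whose codes share a number carried by 0 libraries of other groups, cannot be told apart from the diet either. Normal diet 1 to 3, metformin 1 and unmatched, and resveratrol 1 and 2 also share a number within their group, and what the number stands for is not given in the sources used here. No biological explanation was tested.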

How the results depend on the processing

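The fits without doubted libraries, with covariates, with lncRNA scaling factors and without libraries of groups not compared were added after the data were seen, and the other settings were fixed beforehand. Counts of called mRNA genes are given in the order HFD against normal diet, metformin against HFD, resveratrol against HFD, metformin against resveratrol, metformin against normal diet and resveratrol against normal diet, where edgeR gave 1531, 179, 395, 0, 1 and 0. DESeq2 gave 3129, 2234, 2313, 6, 328 and 146, containing 1525, 179 and 392 of the first 3 sets. RLE normalisation gave 1523, 121, 387, 0, 1 and 0. No filter gave 1055, 0, 214, 0, 0 and 0, a filter at 5 CPM 1564, 233, 529, 0, 0 and 0, a fit of the 2 groups alone 4577, 1142, 0, 0, 28 and 0, a surrogate variable 2318, 0, 2, 0, 29 and 1, and the 2-fold threshold 611, 107, 267, 0, 1 and 0. Leaving out resveratrol 4 gave 4050, 2442, 732, 2, 299 and 26, both unmatched libraries 1596, 458, 710, 1, 0 and 0, all 3 of these 4410, 2639, 1855, 2, 131 and 8, and resveratrol 4 with metformin 2 4979, 1106, 1317, 2, 423 and 120. Without the 6 tract libraries the counts were 4285 for HFD, 17 for resveratrol against HFD (4 shared) and 41 for resveratrol against normal diet. With the 1 metformin library left, assumed to vary like the other groups, they were 18 (2 shared), 3 and 33 against HFD, resveratrol and normal diet. Tract covariates without resveratrol 4 gave 5283, 72 (14 shared), 1925, 3, 555 and 249, where leaving it out alone gave the values above. Leaving out any 1 of the 16 libraries gave 375 to 4050, 0 to 2442, 0 to 915, 0 to 2, 0 to 299 and 0 to 26. The cause of these differences was not tested.

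For lncRNAs, in the order of the first 4 comparisons, edgeR gave 2992, 18, 425 and 0. DESeq2 gave 4420, 1288, 2532 and 23, RLE 3020, 16, 400 and 0, no filter 1146, 0, 1 and 0, the 5 CPM filter 1902, 135, 976 and 0, the 2 groups alone 5719, 39, 7 and 5, a surrogate variable 4771, 339, 285 and 0, and the 2-fold threshold 1465, 13, 265 and 0. Factors of the lncRNA table itself gave 619, 3, 32 and 0. Leaving out resveratrol 4 gave 5596, 1239, 537 and 0, both unmatched libraries 2393, 86, 369 and 1, all 3 of these 5437, 1220, 1186 and 1, resveratrol 4 with metformin 2 5767, 104, 573 and 0, the 6 tract libraries 4291, 113, 25 and 91 with 1 metformin library left, and tract covariates without resveratrol 4 5878, 39, 1023 and 0. Leaving out any 1 library gave 1083 to 5596, 0 to 1239, 1 to 868 and 0 to 1.

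Of the gene lists, 13, 13, 14 and 16 were called in the first 4 comparisons. With an estimated correlation 0 were called in each, against 13, 13, 14 and 16 with RLE. They were 16, 12, 12 and 16 without resveratrol 4, 13, 14, 11 and 11 without the unmatched libraries, and 12 to 16, 12 to 15, 11 to 16 and 7 to 18 when any 1 library was left out. The correlations of fold changes across genes were -0.73, -0.77 and 0.83, and were -0.63, -0.65 and 0.73 with halved HFD libraries. Without resveratrol 4 they were -0.72, -0.82 and 0.76, where unchanged groups gave -0.50, -0.46 and 0.46. Over called genes they were -0.85, -0.88 and 0.96, which tests nothing, since these genes were selected on the same fold changes. Sign changes occurred in named genes that were never called. Adipoq with metformin, at -0.01 on the log2 scale, became 0.015 with the 5 CPM filter, 0.0061 with the 2 groups alone, 1.19 with a surrogate variable, 0.15 without HFD unmatched, without both unmatched libraries and without those and resveratrol 4, 0.18 without metformin 2 with or without resveratrol 4, 0.55 without the 6 tract libraries and 0.58 with covariates and without resveratrol 4, with a range of -0.25 to 0.18 when 1 library was left out. Adipoq with resveratrol, at 0.01, became -0.0286 with no filter and ran from -0.37 to 0.41 when 1 library was left out, below 0 when HFD 1 (-0.04), 2 (-0.04) or 3 (-0.02), metformin 2 (-0.0026) or resveratrol 1 (-0.18) or 3 (-0.37) was left out. Pparg on HFD, at -0.12, became 0.0379 without normal diet 4, in a range from -0.26 without normal diet 2. Of the values of named genes under the settings fixed beforehand, 834 kept direction and call, 515 lost the call, 15 gained one and 12 changed sign. Under added ones the counts were 1096, 263, 21 and 6. At this depth and spread, 22% of simulated 2-fold changes and 63% of 4-fold changes on HFD were found, so a missing call does not show an unchanged gene. No paired analysis was possible because the replicate numbers were given in the order of the samples and pair nothing.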

Other observations

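The tests of other splits below were written before their result was seen, and the per-library values of lncRNAs and of Cyp2e1 were chosen only after the result was seen. Several lncRNAs were near 0 in some libraries and high in others of the same tissue. NONMMUT040716.2 had 19.1 to 27.8 CPM in the 4 normal diet, 4 metformin and first 3 resveratrol libraries, and 0.253 to 0.479 CPM in the 4 HFD libraries and in resveratrol 4. NONMMUT067324.2, within the span of Maf, had 0.213 to 0.387 CPM in the 4 normal diet libraries, 35.7 to 49.0 CPM in all HFD and metformin libraries and in resveratrol 1 and 3, and 0.348 and 0.137 CPM in resveratrol 2 and 4. NONMMUT073617.2, within Magt1, had 15.2, 13.4, 0.267 and 13.2 CPM in normal diet 1 to 4, 20.4 to 23.3 CPM in the HFD libraries and 0.320 to 0.616 CPM in those with resveratrol, but 13.015 and 14.1 CPM in metformin 1 and 2 and 0.356 and 0.273 CPM in metformin 4 and unmatched.

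Within the list of liver and similar markers, single members differed in where they were high. Cyp2e1, a cytochrome P450 of liver that fat also expresses, had 2499 to 4110 CPM on the normal diet, 153 to 229 CPM in HFD 1 to 3, 1435 CPM in HFD unmatched, 770 to 1365 CPM with metformin, 1243 to 2237 CPM in resveratrol 1 to 3 and 35.8 CPM in resveratrol 4. Albumin (Alb) had 1096 CPM in metformin 4 and 7.55 to 418 CPM elsewhere.

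The libraries of each comparison were divided in all 35 ways into 2 groups of 4, or of 4 and 3 for resveratrol without resveratrol 4. For HFD against normal diet, 1 of 35 splits, the real one, gave as many genes (1531, highest other 168). The same held for metformin against HFD (1 of 35, with 179 against 1). No share smaller than 1 of 35 was possible and these tests were not adjusted for their number, so ranking first does not exclude chance. For resveratrol against HFD, 2 of 35 gave as many genes (395, highest other 426, which set HFD 1 to 3 and resveratrol 4 against the rest), so chance cannot be excluded there either. For metformin against normal diet, 3 of 35 did (1, highest other 676, which set normal diet 1, 3 and 4 and metformin 1 against the rest), and that number points to a structure of the samples, since the libraries rich in ciliated epithelium genes stood on the other side. Between the drugs and for resveratrol against normal diet 35 of 35 did, since the real counts were 0 (highest others 1 and 7). For lncRNAs 1 of 35 did for HFD (2992, highest other 1), metformin (18, highest other 2) and resveratrol against HFD (425, highest other 142), and 35 of 35 between the drugs (0, highest other 3). Without resveratrol 4, 1 of 35 did for HFD (4050, highest other 769) and metformin (2442, highest other 415), and 2 of 35 for resveratrol (732, highest other 2174, which set HFD 1 to 3 against the rest), again a structure of the samples.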
